A study of Mus musculus with 4 samples.

How the data were processed

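RNA from regenerating mouse liver was measured on 4 single-colour expression arrays. Per the labels, 2 arrays came from mice given a control siRNA (siControl) and 2 from mice given an siRNA against Orm1 (siOrm), and the replicate numbers were taken from the titles. The titles of the siOrm arrays can also be read as naming siRNAs against Orm1 and Orm2; the source names and descriptions put both arrays in 1 group, and they were treated as replicates. The series text names the Affymetrix Mouse Genome 430A 2.0 array, and the probe set names are of that maker. The labels' protocols name a labelling method of another maker and an extraction from cultured cells, so the laboratory steps are uncertain. No label says whether an array stands for 1 mouse or a pool, so p-values measure only the spread between these samples, which may be technical.

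The deposited table held 18852 probe sets and 4 columns of log2 signal, from which the median of the 4 arrays had been subtracted for each probe set. The largest row median differed from 0 by 4.8e-07. The software, the normalization between arrays and the filter on probe sets are not given in the sources used here. Because of the centring, signal level, background and saturation cannot be seen, and no filter on dim probe sets could be set. The precision is limited by the number of arrays.

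The base of the logarithm is not stated. The values are differences of single-precision numbers, and their smallest steps show the size of the logarithms before centring. With a tolerance of 0.05 steps, 36.3% of probe sets held only whole multiples of the step that belongs to log values of 8 or more, part of them by chance; the share estimated at log values of 8 or more was 24.5%. A base of 10 is excluded by that share. Base 2 was taken as the usual one; with natural logarithms every difference would be 1.44 times larger in log2 units.

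Probe sets were named through the platform's annotation table. Of the probe sets, 17209 had 1 gene symbol, 564 had several, 1044 were not listed there and 35 were control probe sets. Those with 1 symbol gave 10923 genes, 6864 of them from 1 probe set; of these genes 10907 were found by gene number in the gene table of the GRCm38.p6 assembly, and no symbol needed an update. The value of a gene was the mean of its probe sets, which was the rule set for a centred table.

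Differences are siOrm minus siControl. They were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The plan, set before the data were examined, had a variance prior that follows the mean signal. In a centred table that mean is a function of the same 4 values and not a signal level, so a constant prior was used, and the count with the planned prior is given beside the main one. The prior had 3.60 degrees of freedom beside 2 residual ones. For 2 arrays against 2, chance puts both arrays of 1 group above both of the other in 16.7% of genes each way.

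Before the data were examined, 32 gene lists were written down. They held 712 symbols, some of them older and newer names of the same histone gene, and gave 559 measured genes. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 32 lists. Planned as alternatives were the same test with a correlation estimated from these arrays and limma's fry. The estimated form also takes its p-value from the 2 residual degrees of freedom, where the preset form uses the number of genes. Fry asks whether a list's genes move one way on balance without comparing them with other genes. Within each list the gene p-values were also adjusted over the list alone. Named genes followed a rule set in advance. It took Orm1, Orm2 and Orm3, then up to 12 genes each way that passed the test with both siOrm arrays on one side. Free places went to the largest differences with an unadjusted p under 0.01 and the same separation, described as not past the test. It also took up to 4 members of each list, those with the smallest p, and any gene alone in a small count.

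The tests were checked on simulated data drawn from the fitted variances of the 10923 genes, with 2 arrays against 2. Over 20 simulations, 44.8% of genes changed by 1 log2 unit and 95.2% of those changed by 2 were recovered. With no change anywhere, the constant prior called 0.05 genes on average and gave 1.01% of genes an unadjusted p under 0.01. The prior with a trend called 0.3 genes and gave 1.38%, and trend with robust estimation called 135 genes. In 200 simulations of a list of 35 genes without a shift, camera with the preset correlation passed an unadjusted 0.05 in 2.5% when genes varied independently and in 42% when they shared a correlation of 0.25. With an estimated correlation the latter share was 1.5%. A shift of the list by -0.5 with independent genes was found in 100% by both. No shifted list with correlated genes was simulated, so how often either form finds such a shift is not known.

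Alternatives covered quantile normalization, median centring of arrays, the variance prior, the replicate number as a block, leaving out each array in turn, other thresholds, all probe sets, other list tests, probe sets that can share sequence with other genes, and genes from high log values; the last 2 were chosen after the data were seen.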

Results

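Gene expression was measured in the livers of male C57BL6/J mice aged 6 to 13 weeks. The mice received 1 injection of siRNA in a lipid reagent that carries it to the liver, and 3 days later 40% of the liver was removed. Livers were taken 48 hours after this partial hepatectomy, an operation after which the remaining hepatocytes re-enter the cell cycle. There were 2 arrays of siControl livers and 2 of siOrm livers. The series set out to find genes that depend on Orm1, which encodes orosomucoid, an acute phase protein secreted by hepatocytes. All values below are log2 signals relative to the median of the 4 arrays, or differences between group means of such values, with base 2 assumed.

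The targeted gene differed little between the groups. Orm1, measured by 1 probe set, stood at 0.02 and 0.19 in the siControl arrays and at -0.24 and -0.02 in the siOrm arrays. The difference was -0.23 with a standard error of 0.15 and a 95% interval from -0.60 to 0.15, and it did not pass the test (limma, adjusted p = 0.994). It was -0.12 without siOrm replicate 1 and -0.14 without siControl replicate 2. Its paralogs, whose transcripts are very similar, lay further apart. Orm2 differed by -1.08 (SE 0.34; 0.16 and 0.90 against -0.94 and -0.16), and Orm3 by -0.91 (SE 0.34; 0.15 and 1.20 against -0.31 and -0.15); neither passed over all genes (adjusted p = 0.994). Orm2 stood at -0.71 without siControl replicate 2 and at -0.69 without siOrm replicate 1. Orm3 stood at -0.39 without siControl replicate 2, and at -1.43 without siControl replicate 1, where siControl replicate 2 alone stands for its group. For these 3 genes both siOrm arrays lay below both siControl arrays, and 0 of the 3 passed when adjusted over the list alone. As a list the orosomucoids fell, with a mean of -0.74 (adjusted p = 0.00302 by camera, adjusted p = 0.437 with an estimated correlation), and without siControl replicate 2 the mean was -0.41. The labels are therefore checked only weakly by the targeted gene.

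**Figure D1:**
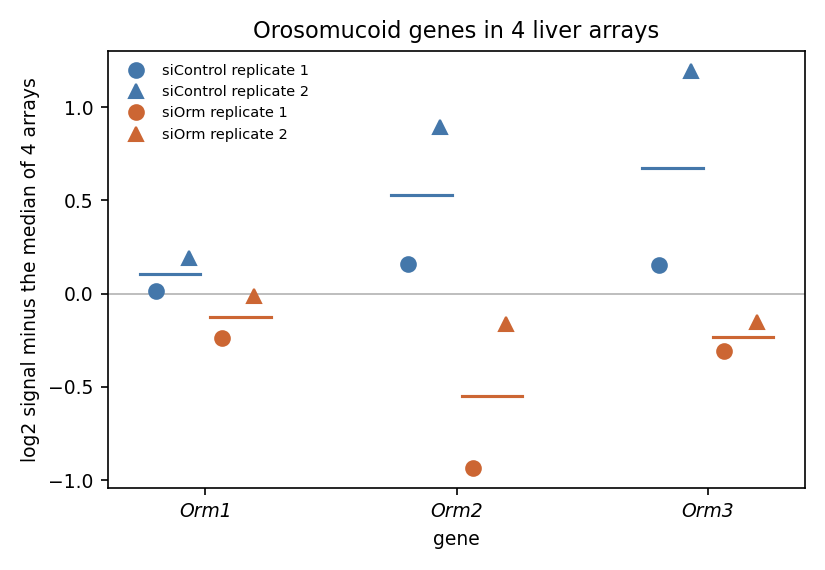
Log2 signal of Orm1, Orm2 and Orm3 relative to the median of the 4 arrays (y axis) for each array; circles are replicate 1, triangles replicate 2, and short lines the group means (n = 2). Orm1 spans -0.24 to 0.19, while siControl replicate 2 reaches 0.90 for Orm2 and 1.20 for Orm3.

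No single gene passed the test between the groups. Of 10923 genes, 0 were higher and 0 were lower in siOrm at an adjusted p under 0.05 (limma), and the smallest adjusted p was 0.857. At an unadjusted p under 0.05 there were 238 genes higher and 282 lower, 520 in all, where chance gives 546. Both siOrm arrays lay above both siControl arrays for 17.0% of genes and below them for 15.3%, where chance gives 16.7% each way. The variance prior with a trend that had been planned called 11 genes. It put Cyp4a14, Dct and Clec2h higher, and Tuft1, Sdf2l1, Bcl3, Onecut1, Ccn2, Gm6958, Osmr and Fdps lower. Without siControl replicate 1 the constant prior called genes both ways, but that fit sets siControl replicate 2 alone against the siOrm arrays.

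The genes with the largest differences among those with an unadjusted p under 0.01 are given by value, since none passed the adjusted test (limma, adjusted p of at least 0.857). On the higher side, Acot3, a peroxisomal acyl-CoA thioesterase, differed by 2.06 (SE 0.46), and Cyp4a14, a fatty acid hydroxylase, by 1.75 (SE 0.27). Elovl3, a fatty acid elongase, differed by 1.29 (SE 0.24), and Angptl4, an inhibitor of lipoprotein lipase, by 0.95 (SE 0.17). The organic anion transporter Slco1a4 differed by 1.37 (SE 0.31). The others were Dct at 1.497, N4bp2l1 at 1.49, Clec2h at 1.22, Cyp2g1 at 1.08, Map2k6 at 1.03, Leap2 at 0.89 and Car1 at 0.87. Acot3 stood at 1.34 without siOrm replicate 1, and N4bp2l1 at 0.91 without siControl replicate 2.

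On the lower side, Onecut1, a liver transcription factor, differed by -1.62 (SE 0.28) and Nucb2 by -1.57 (SE 0.36), or by -1.04 without siOrm replicate 1. The endoplasmic reticulum proteins Creld2 and Sdf2l1 differed by -1.46 (SE 0.37) and -1.40 (SE 0.22). The cell cycle genes Mcm5, Birc5 and Cdc20 differed by -1.28, -1.25 and -1.23. Hamp, which encodes the iron hormone hepcidin, differed by -1.27 (SE 0.22), and Scara5, a ferritin receptor, by -1.19 (SE 0.16). Btg2 differed by -1.30, Tubb6 by -1.25 and Tuft1 by -1.24. Tuft1 was the most even of these, at 0.60 and 0.60 against -0.60 and -0.68.

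The 4 arrays were not equally alike. The standard deviation over genes of the difference between arrays was 0.384 for the siControl pair and 0.249 for the siOrm pair. Between groups it ran from 0.233 to 0.428, so the siControl arrays differed from each other by more than siControl replicate 1 differed from either siOrm array. After quantile normalization that order was lost, with 0.311 for the siControl pair against 0.319 and 0.311 between siControl replicate 1 and the siOrm arrays. The step gives every array the same spread of centred values, so the loss of order does not tell why siControl replicate 2 stood apart. In siControl replicate 2, 137 genes lay above 1, against 12, 12 and 0 in siControl replicate 1, siOrm replicate 1 and siOrm replicate 2.

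The mitosis and DNA replication lists were lower in the siOrm livers at the preset correlation. The mitosis list fell by 0.515 on average (SD over genes 0.38, camera adjusted p = 7.43e-19, adjusted p = 0.379 with an estimated correlation of 0.248). In the simulations, 42% of unshifted lists of 35 genes with a correlation of 0.25 passed an unadjusted 0.05 at the preset correlation. Of the 35 measured mitosis genes, 28 had both siOrm arrays below both siControl arrays and 0 above. None passed over all genes, and 5 were lower when adjusted over the list alone. Cdc20, an activator of the anaphase-promoting complex, differed by -1.23 (SE 0.19). Birc5, which encodes survivin, differed by -1.25 (SE 0.23), Ccnb2, a cyclin of mitosis, by -1.005 (SE 0.21) and Cdca3 by -0.84 (SE 0.16). The list means were 0.14 and 0.45 in siControl and -0.27 and -0.17 in siOrm.

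The DNA replication list fell by 0.409 (camera adjusted p = 1.13e-11, adjusted p = 0.387 with an estimated correlation of 0.303), and by 0.235 without siControl replicate 2. Of 42 genes, 25 were separated downwards and 3 upwards, and 0 passed over all genes or adjusted over the list alone. The helicase subunits Mcm4, Mcm6 and Mcm5 differed by -1.57 (SE 0.45), -1.52 (SE 0.46) and -1.28 (SE 0.27), and Rrm2, a subunit of ribonucleotide reductase, by -0.95 (SE 0.23). Mcm4 stood at -0.95, Mcm6 at -0.96 and Rrm2 at -0.62 without siControl replicate 2. Genes that control entry into S phase did not pass as a list (21 genes, mean -0.18, camera adjusted p = 0.0576, 0 adjusted over the list alone), though they did without siControl replicate 1 (mean -0.32, adjusted p = 0.00743) and without siOrm replicate 2 (mean -0.27, adjusted p = 0.0190). Without siControl replicate 2 their mean was -0.039 (adjusted p = 0.745), and without siOrm replicate 1 it was -0.091 (adjusted p = 0.331). Among these, E2f8 differed by -0.85, Ccne1 by -0.36 and Rbl2 by 0.34. The 4 replication-dependent histone genes measured had a mean of 0.00 and a median of -0.07 (camera adjusted p = 0.905, 0 adjusted over the list alone). Macrophage markers were highest in siControl replicate 2 (0.67, against -0.30 in siControl replicate 1 and -0.03 in both siOrm arrays), which also had the highest means of the mitosis and DNA replication lists.

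**Figure D2:**
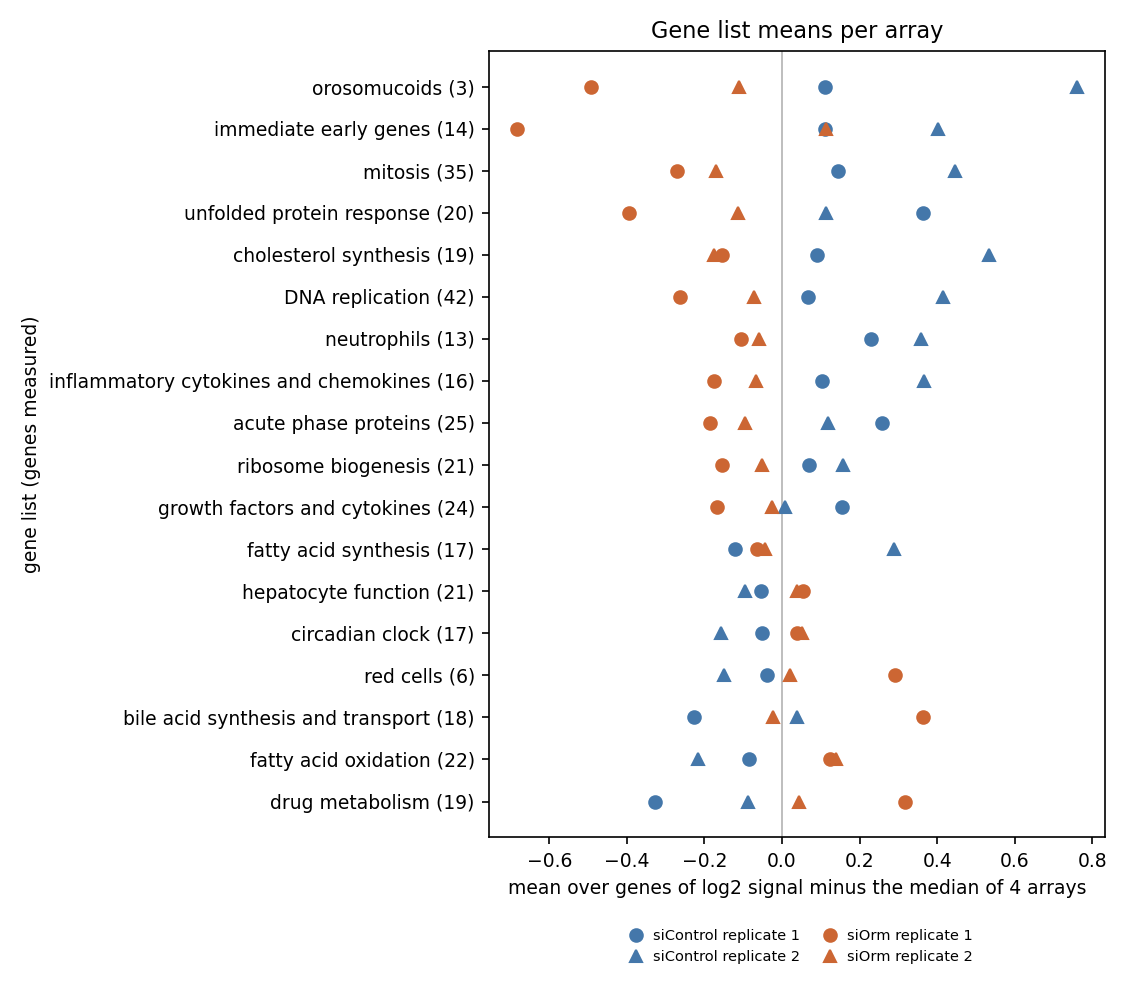
Mean log2 signal relative to the median of the 4 arrays (x axis) for each array, for the 18 gene lists past the preset-correlation test; circles are replicate 1, triangles replicate 2, and numbers in brackets are genes measured. The siOrm arrays lie at -0.27 and -0.17 for mitosis, against 0.14 and 0.45 in siControl.

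Ribosome biogenesis genes fell by 0.216 (21 genes, 11 separated downwards, camera adjusted p = 3.34e-04, adjusted p = 0.379 with an estimated correlation), and 0 passed when adjusted over the list alone. Nop58, a nucleolar protein, differed by -1.32 (SE 0.38), or by -0.78 without siControl replicate 2. Growth factor and cytokine signalling genes fell by 0.177 (24 genes, camera adjusted p = 0.0122, adjusted p = 0.455 with an estimated correlation), with 2 lower when adjusted over the list alone. Osmr, the oncostatin M receptor, differed by -0.90 (SE 0.14), Ccn2, a target of the YAP pathway, by -1.12 (SE 0.17) and Fst, an activin antagonist, by -1.07 (SE 0.27). That call ended without siControl replicate 1, with a mean of -0.10 (adjusted p = 0.372), and without siOrm replicate 1 the mean was -0.11, with Fst at -0.69. The AKT and insulin signalling list did not pass (21 genes, mean -0.04, camera adjusted p = 0.873, 0 adjusted over the list alone). Igfbp1 differed by -0.72, while Irs1, Foxo1 and Foxo3 went the other way, at 0.39, 0.26 and 0.24.

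Immediate early genes fell by 0.540 (14 genes, camera adjusted p = 0.00169, adjusted p = 0.455 with an estimated correlation), with 1 lower, Btg2, when adjusted over the list alone. This rested on siOrm replicate 1, whose list mean was -0.68 against 0.11 in siOrm replicate 2. Without siOrm replicate 1 the mean was -0.14 (adjusted p = 0.375), and without siOrm replicate 2 it was -0.94. After quantile normalization the mean was -0.34 (adjusted p = 0.00602). Jun stood at -2.10 in siOrm replicate 1 and at -0.28 in siOrm replicate 2.

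Acute phase genes other than the orosomucoids fell by 0.329 (25 genes, camera adjusted p = 6.52e-06, adjusted p = 0.379 with an estimated correlation). Of these, 13 were separated downwards and 0 upwards, and 2 were lower when adjusted over the list alone. Hamp differed by -1.27 (SE 0.22), Saa2, a serum amyloid gene, by -1.02 (SE 0.27), Steap4 by -0.98 (SE 0.21) and Il1rn, the interleukin 1 receptor antagonist, by -0.54 (SE 0.14). Inflammatory cytokine and chemokine genes fell by 0.357 (16 genes, camera adjusted p = 0.00384, adjusted p = 0.379 with an estimated correlation, and 0 adjusted over the list alone). Without siControl replicate 2 their mean was -0.23 (adjusted p = 0.0509). Cxcl1 differed by -1.58 (SE 0.48) and Icam1 by -0.87 (SE 0.27). Cxcl1 stood at -0.96 without siOrm replicate 1, and Icam1 at -0.56 without siControl replicate 2. Neutrophil genes fell by 0.376 (13 genes, camera adjusted p = 0.0303, adjusted p = 0.379 with an estimated correlation, and 0 adjusted over the list alone). S100a8 stood at 2.75 in siControl replicate 2 and between -0.60 and 0.16 in the other arrays. The neutrophil call ended without siOrm replicate 2 (mean -0.40, adjusted p = 0.120) and without probe sets that can share sequence with other genes (mean -0.23, adjusted p = 0.175).

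The unfolded protein response list fell by 0.491 (20 genes, camera adjusted p = 3.02e-10, adjusted p = 0.379 with an estimated correlation). It had the most members past its own adjustment, with 10 lower and 1 higher when adjusted over the list alone. The chaperone genes Sdf2l1, Manf, Hspa5 and Dnajb9 differed by -1.40 (SE 0.22), -1.14 (SE 0.19), -0.87 (SE 0.18) and -0.60 (SE 0.15). Unlike those of mitosis and DNA replication, its highest mean was in siControl replicate 1 (0.36, against 0.11 in siControl replicate 2 and -0.39 and -0.11 in siOrm).

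Cholesterol synthesis genes fell by 0.478 (19 genes, 13 separated downwards and 1 upwards, camera adjusted p = 1.28e-08, adjusted p = 0.379 with an estimated correlation), and by 0.256 without siControl replicate 2. Fdps, the farnesyl diphosphate synthase gene, was the 1 gene lower when adjusted over the list alone, at 0.43 and 0.59 against -0.43 and -0.54. Mvd differed by -0.97 (SE 0.29), Cyp51 by -0.76 (SE 0.19) and Lss by -0.46 (SE 0.13). Mvd stood at -0.53 without siControl replicate 2, and Lss at -0.29 without probe sets that can share sequence with other genes. Fatty acid synthesis genes were near the threshold, with a mean of -0.14 (17 genes, camera adjusted p = 0.0487, adjusted p = 0.458 with an estimated correlation, and 0 adjusted over the list alone). Without siControl replicate 2 the mean turned to 0.07, and without siControl replicate 1 it was -0.34. The call ended without siOrm replicate 2 at a similar mean of -0.15. It also ended after quantile normalization, where the mean shrank to -0.09 (camera adjusted p = 0.0783). Acly differed by -0.69 (SE 0.22), or by -0.41 without siControl replicate 2, and Acaca by -0.35 (SE 0.14). Me1 went the other way, at 0.27 (SE 0.13).

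Fatty acid oxidation genes rose by 0.281 on average (22 genes, 14 separated upwards and 1 downwards, camera adjusted p = 2.49e-06, adjusted p = 0.379 with an estimated correlation), with 2 higher when adjusted over the list alone, Cyp4a14 and Angptl4. Acot1 differed by 0.98 (SE 0.32), or by 0.49 without siControl replicate 2, and Acaa1b by 0.45 (SE 0.14). Their list means were -0.09 and -0.22 in siControl and 0.12 and 0.14 in siOrm.

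Drug metabolism genes rose by 0.389 (19 genes, 9 separated upwards and 0 downwards, camera adjusted p = 1.39e-05, adjusted p = 0.379 with an estimated correlation, and 0 adjusted over the list alone), and by 0.252 without siOrm replicate 1. Ces1d, a carboxylesterase, differed by 0.82 (SE 0.20) and Cyp2c38 by 0.61 (SE 0.19), or by 0.37 without siControl replicate 2, while Cyp2b9 stood at 2.74 in siOrm replicate 1 and at 0.22 in siOrm replicate 2. Bile acid genes rose by 0.265 (18 genes, camera adjusted p = 0.00792, adjusted p = 0.379 with an estimated correlation, and 0 adjusted over the list alone). Slc10a1, the bile salt importer, differed by 0.66 (SE 0.24), or by 0.37 without siOrm replicate 1. The bile acid call ended without siControl replicate 1 (mean 0.13, adjusted p = 0.398) and without siOrm replicate 1 (mean 0.07, adjusted p = 0.331), and the mean was 0.40 without siControl replicate 2 and 0.46 without siOrm replicate 2.

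The hepatocyte function list was near the threshold, with a mean of 0.12 (21 genes, camera adjusted p = 0.0487, adjusted p = 0.458 with an estimated correlation, and 0 adjusted over the list alone). Its mean lay between 0.10 and 0.14 when any 1 array was left out and was 0.13 after quantile normalization (camera adjusted p = 0.106). The call ended in each of these settings, with a similar mean. G6pc, the last enzyme of glucose production, differed by 1.34 (SE 0.36), or by 0.86 without siControl replicate 1. Tat went the other way, at -0.44 (SE 0.26), or at -0.06 without siOrm replicate 1. Circadian clock genes rose by 0.150 (17 genes, camera adjusted p = 0.0328, adjusted p = 0.379 with an estimated correlation, and 0 adjusted over the list alone), a call that ended without siControl replicate 2 (mean 0.10, adjusted p = 0.139) and without siOrm replicate 2 (mean 0.14, adjusted p = 0.108). Usp2 and Cry2 differed by 0.66 (SE 0.20) and 0.52 (SE 0.17), and Usp2 by 0.39 without siControl replicate 1. Bhlhe40 went the other way, at -0.36 (SE 0.13), with both siOrm arrays below both siControl arrays.

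In all, 12 lists were lower and 6 higher in siOrm at the preset correlation. With a correlation estimated from the arrays 0 of these 18 lists passed, with adjusted p from 0.379 to 0.575 over the 18, and by fry 0 lists passed, with a smallest adjusted p of 0.406. Estimated correlations of the called lists ran up to 0.84 for the orosomucoids, with 0.36 for the unfolded protein response and 0.33 for cholesterol synthesis. The cytokine, neutrophil and circadian clock lists had estimated correlations of -0.039, -0.059 and -0.0034, below the preset 0.01, and still lost their calls. Correlation between genes therefore does not account for every loss. The estimated form also takes its p-value from the 2 residual degrees of freedom, which raises it whatever the correlation. How much of a loss is due to correlation is not shown by these values. Over the 4258 genes with the numeric step of log values of 8 or more, a choice made after the data were seen, 14 of the 18 lists had at least 3 genes and 6 passed. These were acute phase, DNA replication, cholesterol synthesis, the unfolded protein response, fatty acid oxidation and drug metabolism. The calls of bile acid, circadian clock, fatty acid synthesis, growth factor, hepatocyte function, immediate early, cytokine and ribosome biogenesis genes ended there. The means of the immediate early, cytokine and ribosome biogenesis lists shrank to -0.14, -0.15 and -0.10, and that of the growth factor list was 0.0032. Those of the bile acid, circadian clock, fatty acid synthesis and hepatocyte function lists stayed near their main values, at 0.24, 0.15, -0.16 and 0.12. The mitosis list, with 2 such genes among 35, and the orosomucoid, neutrophil and red cell lists were not tested there. With camera on ranks the calls of fatty acid synthesis (adjusted p = 0.073), growth factor (adjusted p = 0.0609) and red cell genes (adjusted p = 0.0516) ended.

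Of the lists of markers of other liver cells, those of macrophages, stellate cells, endothelium and bile duct had their highest means in siControl replicate 2. So did the neutrophil and fat lists, at 0.36 and 0.39. The Kupffer cell and macrophage list stood at -0.30 in siControl replicate 1, 0.67 in siControl replicate 2 and -0.03 in both siOrm arrays. Its mean difference of -0.22 did not pass (22 genes, camera adjusted p = 0.219) and was -0.094 after quantile normalization. Without siControl replicate 2 it was 0.27 (adjusted p = 2.51e-07), and without siControl replicate 1 it was -0.70 (adjusted p = 1.65e-10). Marco, a macrophage scavenger receptor, stood at 1.97 in siControl replicate 2 and at 0.25 or less in the others. Stellate cell and matrix genes had a mean difference of -0.095 (18 genes, camera adjusted p = 0.345), and sinusoidal endothelium genes one of -0.03 (17 genes, camera adjusted p = 0.624). These also changed sign without siControl replicate 2, to 0.24 and 0.18 (both adjusted p = 9.16e-04), and stood at -0.43 (adjusted p = 1.22e-04) and -0.25 (adjusted p = 0.00172) without siControl replicate 1. Both were above 0 after quantile normalization, at 0.05 and 0.02. Bile duct genes had a mean of -0.07 and a median of 0.05 (9 genes, camera adjusted p = 0.905), and the mean turned to 0.02 after quantile normalization. In the macrophage, stellate cell, endothelial and bile duct lists 0 genes passed when adjusted over the list alone.

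**Figure D3:**
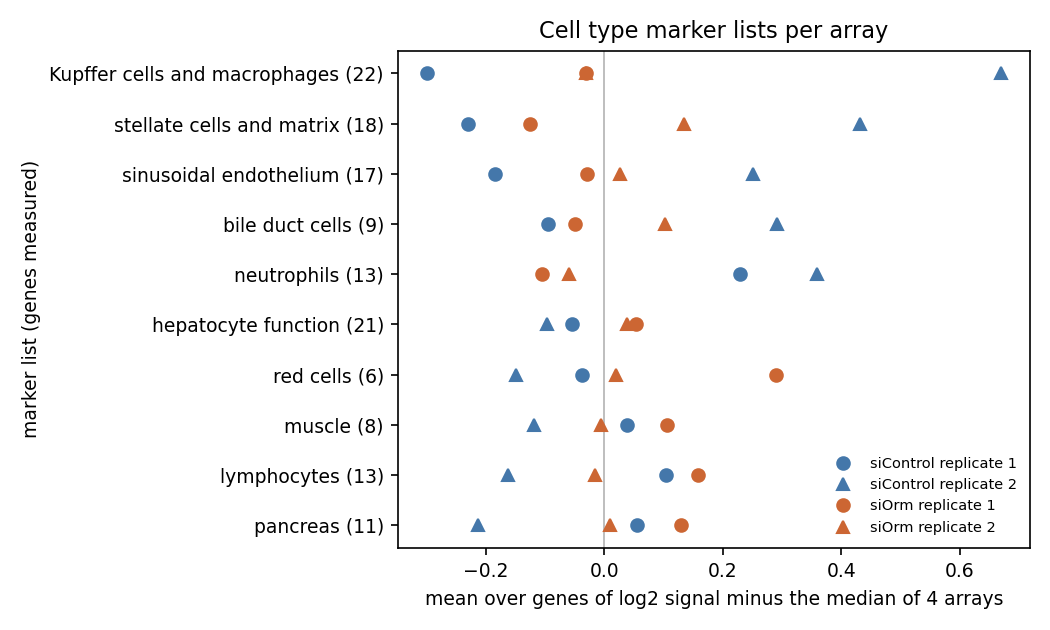
Mean log2 signal relative to the median of the 4 arrays (x axis) for each array, for 9 lists of cell type markers and the hepatocyte function list; circles are replicate 1, triangles replicate 2, and numbers in brackets are genes measured. Macrophage markers stand at 0.67 in siControl replicate 2 and at -0.30, -0.03 and -0.03 in the other arrays.

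Red cell genes rose by 0.249 (6 genes, camera adjusted p = 0.0195, adjusted p = 0.575 with an estimated correlation), and Alas2, a heme synthesis gene of red cell precursors, was the 1 gene higher when adjusted over the list alone, by 0.62 (SE 0.13). That call ended without siControl replicate 2 (mean 0.19, adjusted p = 0.122), without siOrm replicate 1 (mean 0.11, adjusted p = 0.309) and without probe sets that can share sequence with other genes (mean 0.16, adjusted p = 0.1005), and the mean was 0.38 without siOrm replicate 2. The lymphocyte list (13 genes, mean 0.10, camera adjusted p = 0.0936) and the pancreas list (11 genes, mean 0.15, camera adjusted p = 0.0554) did not pass. Without siControl replicate 1 both did, at 0.23 (adjusted p = 0.00893) and 0.28 (adjusted p = 0.00815), and likewise without siOrm replicate 2, at 0.19 (adjusted p = 0.0132) and 0.21 (adjusted p = 0.0299). Without siControl replicate 2 they stood at -0.034 (adjusted p = 0.661) and 0.013 (adjusted p = 0.838), and without siOrm replicate 1 at 0.012 (adjusted p = 0.910) and 0.089 (adjusted p = 0.331). The fat list (4 genes, mean -0.13, camera adjusted p = 0.495) and the muscle list (8 genes, mean 0.09, camera adjusted p = 0.278) did not pass. None of these 4 lists had a gene past the threshold when adjusted over the list alone.

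The NRF2, interferon and p53 lists did not pass between the groups. Targets of the antioxidant regulator NRF2 had a mean difference of -0.22 (15 genes, camera adjusted p = 0.0722), interferon response genes one of -0.15 (29 genes, camera adjusted p = 0.612) and p53 targets one of -0.08 (15 genes, camera adjusted p = 0.278). In each, 0 genes passed when adjusted over the list alone. Without siControl replicate 1 the means were -0.59 (adjusted p = 7.05e-06), -0.42 (adjusted p = 7.01e-04) and -0.20 (adjusted p = 0.0291). Without siControl replicate 2 they turned to 0.15 (adjusted p = 0.1004), 0.13 (adjusted p = 0.00919) and 0.04 (adjusted p = 0.708). The NRF2 list passed also without siOrm replicate 2 (mean -0.28, adjusted p = 0.0482). Gstm3, a glutathione transferase, stood at 2.64 and Cxcl9 at 2.51 in siControl replicate 2, against -0.59 to 0.10 for both genes in the other arrays. Gsta3, the NRF2 target with the smallest p, went the other way from its list mean, at 0.46 (SE 0.16). Ifi47, an interferon-induced GTPase, differed by -0.83 (SE 0.15), and Ifit2 of the same list by 0.48 (SE 0.24). The p53 targets Cdkn1a and Gadd45a differed by -0.60 (SE 0.22) and 0.90 (SE 0.27). Cdkn1a stood at -0.30 without siControl replicate 2, and Gadd45a at 0.55 without siOrm replicate 1.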

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

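Chosen after the results were seen were the tests on control probe sets, the interval of the mitosis list against siControl replicate 1, its comparison with macrophage markers and with other splits of the arrays, the count of acute phase genes below the Orm genes, and the comparisons between the siControl arrays other than the one after quantile normalization.

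Outside the gene comparisons, 2 control probe sets for mouse B2 repeats stood higher in both siOrm arrays than in both siControl arrays. The difference was 0.14 for MUR_b2 and 0.071 for MURINE_B2. Beta-actin control probe sets were separated the other way and by more, at 0.09 and 0.61 in siControl against -0.26 and -0.09 in siOrm, a difference of -0.53. Among 9 kinds of control, chance separates 1 in 6 upwards and as many downwards.

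The mitosis list was lower in siOrm by 0.52 on the log2 scale, and an effect of the siRNA stays open. Over all arrays it passed at the preset correlation (camera adjusted p = 7.43e-19) but not with an estimated one (adjusted p = 0.379). Against siControl replicate 1 alone the difference was -0.36, lower in 33 of 35 genes. The spread between arrays left for that comparison is that of the siOrm pair (SE 0.087, 1 degree of freedom, 95% interval from -1.47 to 0.74), so whether siControl replicate 2 carries the difference cannot be told apart from a group difference with this few arrays. More macrophages in the siControl livers may also have brought dividing cells; in siControl replicate 1, where macrophage markers were 0.27 below the siOrm arrays, mitosis genes were 0.36 above them, which speaks against that without excluding it over the same interval. Of the 3 splits of the arrays into pairs, 1, the real one, reached this size, with -0.52 against at most 0.20 in the others (camera adjusted p = 0.0398 for 0.20), and 3 splits are too few for a share under 0.05.

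The targeted gene Orm1 differed by -0.23, less than Orm2 and Orm3. A different acute phase state of the livers is a candidate explanation for the lower siOrm means of all 3, and the tables do not decide it. None of the 3 passed over all genes. Of 25 other acute phase genes, 5 lay further down than the mean of the 3, and that list fell at the preset correlation (adjusted p = 6.52e-06, adjusted p = 0.379 with an estimated correlation). From siControl replicate 1 to replicate 2 the Orm genes rose by 0.65 (3 of 3), while the acute phase list moved by -0.14 (8 of 25 higher). Its members moved both ways, with Saa2 from 0.23 to 0.77 and Lcn2 from 0.26 to 1.26, but Hamp from 1.03 to 0.45. The list mean therefore does not settle the matter. A saturated Orm1 probe set, which would hide a larger fall, could not be examined, because no signal level is left (measured -0.23, SE 0.15), and a silencing of the Orm genes by the siRNA stays open as well.

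Replicate 2 of siControl was the array furthest from the median for 41.4% of genes. Compared with siControl replicate 1, it held more signal of macrophage markers (0.97), stellate cell genes (0.66), endothelial genes (0.44) and bile duct genes (0.39). A lower share of hepatocytes would raise the markers of all other cells alike if these cells kept their proportions. Lymphocyte genes instead moved by -0.27 (2 of 13 higher), red cell genes by -0.11 (2 of 6) and neutrophil genes by 0.13 (6 of 13). The hepatocyte function list moved by -0.04 (SE over genes 0.07, 9 of 21 higher). Macrophage markers rose above endothelial ones by a further 0.53 (SE over genes 0.14). These comparisons set 1 array against 1, and an SE over genes measures no spread between livers, so a lower hepatocyte share is not excluded. Scaling of the array was not settled either. Macrophage markers remained 0.69 higher (SE over genes 0.08) after quantile normalization. That step acted on centred values and keeps their order within an array, so it cannot exclude a scaling that follows signal level. A liver with more or activated macrophages may lie behind the distance of this array. That is a hypothesis from 1 array, and the siRNA groups do not test it. Control probe sets of this array also stood apart, as given at the end, and a technical difference was not tested.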

How the results depend on the processing

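Alternatives were chosen before the data were examined, except leaving out probe sets that can share sequence with other genes and using only genes from high log values. Orm1 stayed below 0 and short of the threshold in each alternative run, from -0.34 to -0.12 when 1 array was left out. With 3 arrays, the lone array is assumed to vary like the others. Filters on low mean signal, a floor on low values and the upper genes by mean were not run, since a centred table has no level; the mean of a gene's probe sets was the main setting. With the replicate number as a block, 0 genes were higher and 0 lower, and Orm1 stood at -0.23 (limma, adjusted p = 0.827). At the preset correlation 14 lists were then lower and 7 higher. The lists that joined were S phase entry, NRF2 and pancreas (camera adjusted p = 0.0189, 0.0482 and 0.0334). With an estimated correlation and no block, their adjusted p was 0.575, 0.722 and 0.722 (camera). The differences between arrays correlated by 0.13 across genes between the pairs, and 2 pairs cannot show that the numbers pair the arrays.

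Genes higher and lower numbered 0 and 0. They became 3 and 8 with a trend in the prior, 52 and 80 with trend and robust estimation (a setting that also called 135 genes on average in simulated data without change), and 82 and 138 at an unadjusted p under 0.05 with 1.5-fold. Leaving out 1 array gave 0 to 46 and 0 to 183, the highest without siControl replicate 1. At an adjusted p under 0.10, over all probe sets and in the other settings both stayed at 0. The 12 lower and 6 higher lists became 0 and 0 with an estimated correlation and by fry, so orosomucoids (-0.74), acute phase (-0.33), DNA replication (-0.41) and mitosis (-0.52) lost their calls there with unchanged differences. High-level genes gave 4 and 2 lists, with fewer genes tested, and leaving out 1 array gave 10 to 18 lower and 3 to 7 higher. Of the 18 called lists, 9 passed in each leave-out, 16 after quantile normalization and 15 on ranks. The spread between the siControl arrays, 0.384, was 0.311 after quantile normalization and 0.358 over high-level genes.

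Directions turned as follows, and the cause was not tested. Leaving out 1 array gave these ranges. With siControl replicate 2 left out, the sign turned for macrophages (-0.70 to 0.27), NRF2 (-0.59 to 0.15), fatty acid synthesis (-0.34 to 0.067), interferon (-0.42 to 0.13), lymphocytes (-0.034 to 0.23), p53 (-0.20 to 0.037), endothelium (-0.25 to 0.18), Atp2a1 (-0.024 to 0.21), Fabp4 (-0.70 to 0.12), H1f2 (-0.56 to 0.46) and H3c7 (-0.30 to 0.019). With that array or siOrm replicate 1 left out, it turned for bile duct (-0.27 to 0.12) and stellate genes (-0.43 to 0.24), and with that array or siOrm replicate 2, for fat (-0.32 to 0.054). With either siControl replicate 1 or siOrm replicate 1 left out, it turned for AKT (-0.087 to 0.013) and histones (-0.13 to 0.14). It turned without siOrm replicate 1 for Actn3 (-0.024 to 0.19) and Ighm (-0.0023 to 0.33), and without siControl replicate 1 for H3c4 (-0.29 to 0.12) and Retn (-0.58 to 0.023). After quantile normalization, bile duct stood at 0.022, endothelium at 0.023, stellate at 0.0501 and H1f2 at 0.058. Over high-level genes, growth factor signalling stood at 0.0032. Without probe sets that can share sequence, histones stood at -0.092, Acta2 at 0.23 and Hbb-b2 at -0.058.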

Other observations

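The values of single arrays, the comparisons between arrays of a group and the other groupings of the arrays were chosen after the data were seen.

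Several genes were far higher in siControl replicate 2 than in the other arrays. Picked from the 25 with the widest gap to the next array, the chemokine genes Cxcl10 and Cxcl2 stood at 3.15 and 3.03, Cd14, a receptor for bacterial lipopolysaccharide, at 2.79, and S100a8 and S100a9 at 2.75 and 1.95. Saa3 and Chil3, both made by activated macrophages, stood at 1.99 and 1.96. In the other arrays these 7 genes lay between -0.60 and 0.26. Against siControl replicate 1, all 22 macrophage genes, 24 of 29 interferon response genes and 14 of 15 NRF2 targets were higher in this array, by means of 0.97, 0.56 and 0.73. Inflammatory cytokine and chemokine genes were higher in 9 of 16 (mean 0.26, SE over genes 0.23) and neutrophil genes in 6 of 13 (mean 0.13, SE over genes 0.30). Acute phase genes had a mean of -0.14, with 8 of 25 higher. The 11 genes of the pancreas list had a mean of -0.27, with 0 higher, and the 13 lymphocyte genes also one of -0.27, with 2 higher. Of these, 0 lymphocyte genes and 6 pancreas genes had the numeric step of log values of 8 or more.

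The 2 siOrm arrays differed from each other in the immediate early list, with means of -0.68 and 0.11, and in bile acid genes, with 0.36 and -0.02. Jun at -2.10 and Cyp2b9 at 2.74 in siOrm replicate 1 were among the widest gaps between these arrays in the named genes.

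Grouping the arrays in the other ways gave 502 and 287 genes at an unadjusted p under 0.05, against 520 for the real groups, and 0 genes at an adjusted p under 0.05 in each. The preset-correlation test passed 13 and 10 of the 32 lists for those groupings, against 18 for the real one. Of the 18 lists called between the real groups, 3 passed with siControl replicate 2 and siOrm replicate 2 as one group. These were DNA replication (0.27, camera adjusted p = 2.97e-04), immediate early genes (0.54, camera adjusted p = 0.00383, against -0.54 for the real groups) and mitosis (0.20, camera adjusted p = 0.0398). With siControl replicate 2 and siOrm replicate 1 as one group 5 passed. These were bile acid genes (0.33, camera adjusted p = 0.0080, against 0.27 for the real groups), the unfolded protein response (-0.27, camera adjusted p = 0.0065), cholesterol synthesis (0.23, camera adjusted p = 0.0111), drug metabolism (0.26, camera adjusted p = 0.0379) and fatty acid synthesis (0.20, camera adjusted p = 0.00896).

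Control probe sets for 18S ribosomal RNA stood at 0.03 and -0.34 in siControl and at -0.03 and 0.42 in siOrm. The difference between 5′ and 3′ probe sets of beta-actin was 0.02 and 0.18 in siControl and -0.04 and -0.02 in siOrm, and that of GAPDH -0.01 and 0.17 against 0.03 and -0.03. Both differences were highest, and 18S ribosomal RNA lowest, in siControl replicate 2, the array that stood apart. Each probe set is centred on its own median, so these values compare arrays only and do not show whether the RNA was intact.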
